A study of Arabidopsis thaliana with 14 samples.

How the data were processed

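RNA from Arabidopsis thaliana seed was measured on 14 single-colour 3' expression arrays. Primary dormant seed of the Landsberg erecta wild type and of the gibberellin-deficient mutant ga1-3 had been imbibed for 24 h at 20 C in light of 100 uE on agar of 0.8%, either plain or with 1 uM KAR1, a butenolide found in smoke. The labels give 4 groups: wild type on water (4 arrays), wild type on KAR1 (4 arrays), ga1-3 on water (3 arrays) and ga1-3 on KAR1 (3 arrays). Each array of a group comes from another harvest of seed, lettered A to D in wild type and A to C in ga1-3.

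The deposited values are 1 intensity per probe set and array, which the authors made with GCRMA (background adjustment, normalization and summary of probes) per the submitters' processing notes, with no version and no statement on whether all arrays were normalized together. Per the labels' protocols, 7 ug of total RNA per sample went into biotin-labelled cRNA by amplification from the 3' end. The deposited intensity is on a linear scale with 1 decimal, from 3.5 to 39328.1, and no scanner values were available, so neither detection calls nor a new normalization from probe level could be had. Arrays have no count of molecules, so no depth can be given. Their number, low signal and shared seed batches limit the precision.

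All 14 columns matched a sample label. Of 22810 probe sets, 64 controls were left out and 22746 were tested. The log2 of the deposited intensity was taken; no value lay below 1. Gene names came from the platform annotation given for these probes. It pairs 13513 probe sets with 1 gene and 503 with several, and lists none for 8730, which are unnamed here rather than without a gene. Of the probe sets with 1 gene, 13436 matched the TAIR10.1 gene table, and 1580 carry a gene name other than the locus. A probe set with several genes was never named by one of them.

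Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit on the means of the 4 groups over all 14 arrays, no block, eBayes with trend and robust, two-sided, 10 residual degrees of freedom per probe set before moderation). A call is a Benjamini-Hochberg adjusted p under 0.05. Unless another test is named, every adjusted p is from this fit, and ± after a log2 difference is its standard error. The 6 contrasts were KAR1 against water in wild type, the same in ga1-3, the difference of these effects (interaction), their mean with equal weight for each genotype, and ga1-3 against wild type on water and on KAR1. Designs, the fixed gene lists and the settings listed last were chosen before the data were examined.

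The labels say that letters name seed batches, so a water array and a KAR1 array of 1 genotype and letter share their seed. Deviations from the group means, over probe sets above the median level, correlated within such pairs at r of 0.855, 0.600, 0.507 and 0.688 for wild type A to D, and at 0.778, 0.610 and 0.557 for ga1-3 A to C. Batches B and C of ga1-3 correlated as well with each other's arrays (up to 0.632 and 0.568) as with their own. A fit with the seed batch as block (5 residual degrees of freedom) is therefore given beside the KAR1 results where it changes a call or a count. A letter shared by both genotypes names different seed and was used as a block in one of the other settings only.

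Scan dates were not used here. The arrays were cut into 3 clusters, a chosen number, by average linkage on the 21 probe sets for transcripts spiked in by the laboratory. They are called hybridisation clusters here. The values are after GCRMA and include poly(A) spikes, so the clusters need not come from hybridisation alone. Cluster 1 holds wild type A and B, cluster 2 wild type C and D with ga1-3 A, and cluster 3 ga1-3 B and C, each with both treatments. The fit with the cluster as an additive block, differences within cluster 2, and a fit without cluster 2 were added after the data had been seen. Cluster 2 holds 1 ga1-3 array per treatment, so the spread in a fit on it comes from wild type alone. Clusters 1 and 3 each hold a single genotype. With the cluster as block, a genotype difference therefore also rests on ga1-3 batch A alone, and its call does not test whether the difference recurs across ga1-3 batches.

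The named genes follow a rule: for each contrast up to 8 calls with 1 gene in each direction, by size, with the same direction in every seed batch or no overlap between genotypes, or the 4 smallest p in each direction where no gene passes; and up to 4 members per gene list. The rule also names GA1, DLK2, KUF1, BBX20, GA3OX1, GA3OX2, DOG1, HY5 and CHS, for which the annotation names no probe set, so the mutated gene could not be looked up as a check of the labels. AT3G52740, HYH, AT2G16365, AT3G60290 and HAT2 were also followed through all contrasts after their values had been seen. The 19 lists fixed beforehand have 285 members, of which 33 were measured under a gene name of the annotation and 2 were dropped because the locus carries another symbol; 6 lists had 3 or more members measured. Another 15 lists were built from the annotation's gene names, after the arrays' distributions and correlations had been seen and before any effect was looked at. Lists were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry.

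Other settings tried were the seed batch block, plain eBayes, leaving out 7582 probe sets with the lowest means, quantile normalization, centring each array on its median, a floor, a fold limit, fits on the compared arrays alone, array weights and leaving out each array in turn. The floor was written as 4 without its scale. It was read as log2 4 (intensity 16), and 12100 probe sets still varied after it. Where the mean of a genotype lies under 16, its fold against the other genotype is given as a bound (at least), from group means with values under 16 raised to 16, with the adjusted p of the fit without floor; no fold is given where both means lie under 16. These bounds were chosen after the data had been seen. Fits were tested on simulated data with 200 changed genes among 22746. The changed genes were drawn from probe sets with a mean at least 2-fold above 16, and no effect of the hybridisation clusters was put in. The shares recovered therefore do not hold for probe sets at lower levels. For the mean KAR1 effect, 34.3% of genes changed by 1.5-fold, 71.6% of those changed 2-fold and 100% of those changed 4-fold were recovered without block, and 76.1%, 95.5% and 100% with the seed batch block. For KAR1 in wild type the shares were 14.9%, 53.7% and 93.9% without block and 44.8%, 85.1% and 98.5% with it. For ga1-3 against wild type on water they were 22.4%, 52.2% and 89.4%. The real genotype fit on water had 8301 calls, far more than the 200 genes changed here. These shares and false calls therefore do not carry over to it. False calls numbered 0 without block and 7 with it for the mean KAR1 effect. For KAR1 in wild type there were 2 without block and 8 with it. For the genotype there were 11 without block, beside 109 true calls.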

Results

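Transcript levels were measured on 14 arrays of seed imbibed for 24 h. Wild type seed had 4 arrays on water and 4 on KAR1, and ga1-3 seed, which makes too little gibberellin to germinate, had 3 on each. The median intensity per array lay between 10.4 and 12.6, and between 46.8% and 47.6% of probe sets lay at 16 or more. Arrays correlated at 0.943 to 0.999 with each other.

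The arrays lay apart by genotype and by seed batch. In ga1-3 the split of batch A from B and C is also one of hybridisation cluster. The first principal component held 69.9% of the variance and placed wild type between -66.1 and -17.6 and ga1-3 between 14.5 and 58.1. Within ga1-3, both arrays of seed batch A lay at 14.5 and 28.0, apart from batches B and C at 55.0 to 58.1. In both arrays of wild type batch A the 69 plastid-encoded transcripts stood above their means over all arrays, by a median of 2.14 on water and 2.01 on KAR1 (log2). In wild type batches B to D this median lay between -0.42 and 0.50. The 5S ribosomal RNA control averaged 10.6 in wild type batch A and 8.21 to 9.81 in the others of wild type.

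**Figure D1:**
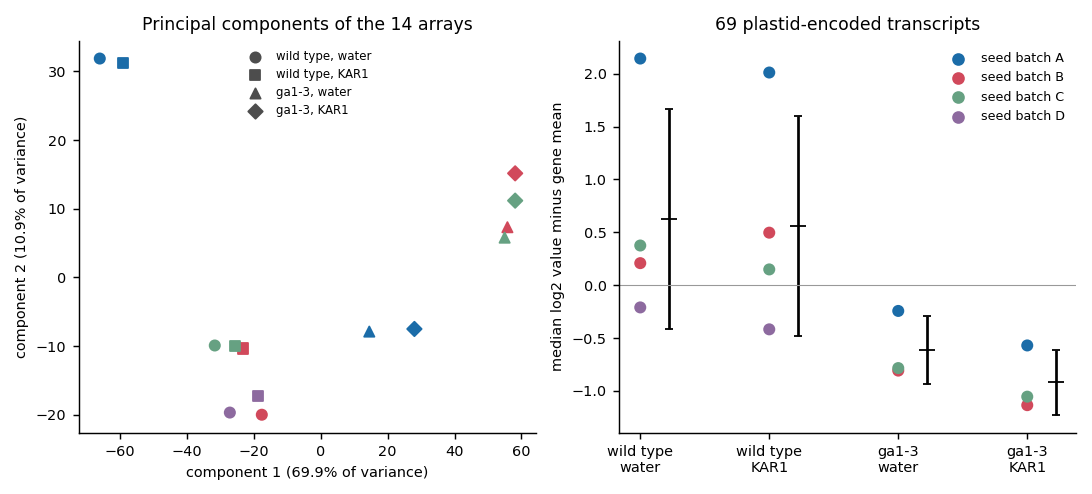
Left, scores of the 14 arrays on principal components 1 (69.9% of variance) and 2 (10.9%), with the group as marker and the seed batch as colour. Right, the median over 69 plastid-encoded transcripts of log2 intensity minus the transcript's mean over all arrays, 1 point per array, with mean and SD per group beside the points; wild type batch A lies above 2 on both treatments.

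Averaged over both genotypes, KAR1 moved a small set of transcripts. The question was which transcripts the compound moves in seed that it helps to germinate and in seed that cannot respond by germinating. AT3G60290, which encodes a 2-oxoglutarate-dependent oxygenase, rose from a mean log2 intensity of 6.15 ± 0.24 (SD, n = 4) to 7.73 ± 0.34 (SD, n = 4) in wild type and from 5.33 ± 0.27 (SD, n = 3) to 7.46 ± 0.89 (SD, n = 3) in ga1-3. Averaged over both genotypes it rose 3.62-fold (log2 1.86 ± 0.24, adjusted p = 0.0378), and all 7 seed batches moved up. AT3G55720 rose 2.62-fold (1.39 ± 0.18, adjusted p = 0.0378) and AT1G25520 1.60-fold (0.67 ± 0.08, adjusted p = 0.0354), each in 7 of 7 seed batches. HAT2, a homeodomain-leucine zipper transcription factor of the auxin and shade responses, fell by 0.74 ± 0.10 (adjusted p = 0.0422), also in 7 of 7, with both wild type means under 16. Genes named by size had to move 1 way in every seed batch, so this is no separate support. The remaining call has no gene in the annotation and rose by 2.02, in 7 of 7. In the fit without block, 1 of the 14 arrays was left out in turn. AT3G60290 then lost its call 10 times (effect 1.60 or more) and AT3G55720 10 times (1.25 or more). AT1G25520 lost it 9 times (0.63 or more) and HAT2 12 times (-0.81 to -0.66). Each such fit leaves 1 seed batch with an array on 1 treatment only. With all arrays and the seed batch as block, the adjusted p was 0.0254 for AT3G60290 and 0.0145 for AT3G55720. It was 0.0214 for AT1G25520 and 0.0424 for HAT2. How stable these calls with the block are when an array is left out was not tested.

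With the seed batch as block, the mean KAR1 effect had 86 calls, 65 up and 21 down, against 5 without block (4 up and 1 down). The balance was less one-sided with array weights (57 up and 33 down) and with the block and the floor together (278 up and 199 down). Selection on the mean over both genotypes partly fixes a shared sign, and 6 of the 86 had an effect under 0.1 in size in 1 genotype; 78 moved the same way in all 7 seed batches. A single gene was named for 38 of them. AT2G16365, whose protein keeps phytochrome B in its active form, rose 2.08-fold (log2 1.06, adjusted p = 0.0424 with the block and 0.0637 without). The cryptochrome inhibitors AT3G52740 and AT3G44450 rose by 0.64 (adjusted p = 0.0214 with the block, 0.144 without) and 0.85 (0.0458 and 0.262). HYH, a bZIP factor of light responses, rose by 0.61 (0.0386 and 0.663); it was 1 of the 2 members measured of the fixed light signalling list, and passed without block when adjusted over the list alone. These 4 genes were put side by side after their values were seen, and the fixed light list was too small to test.

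Larger rises with the block were AT4G35110 at 3.43-fold (adjusted p = 0.0313), AT5G08050 at 2.25-fold (0.0424) and AT1G33590 (0.0214). Each rose in 7 of 7 seed batches, as the naming rule asked. The mean of AT1G33590 in wild type on water lay under 16. The falls with the block were smaller. AT1G03890, of the seed storage cupin family, fell by 0.64 (adjusted p = 0.0285) and AT4G33980 fell by 0.55 (0.0424). XERICO, a RING-type protein that raises abscisic acid levels, fell by 0.45 (0.0458) and AT5G37360 fell by 0.51 (0.0386). GSTU27, a glutathione S-transferase, also passed upward with the block (0.0424), at group means of only 2.26 to 4.04, and its difference was 0.00 in ga1-3 batch B. The light-harvesting protein gene LHCB4.1 fell by 0.27 (0.0488), with effects of -0.02 in wild type and -0.52 in ga1-3 whose difference did not pass. Without block, leaving out the wild type water array of batch C, the wild type KAR1 array of batch C or D, or the ga1-3 water array of batch A or C left 0 calls, and plain eBayes left 1.

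**Figure D2:**
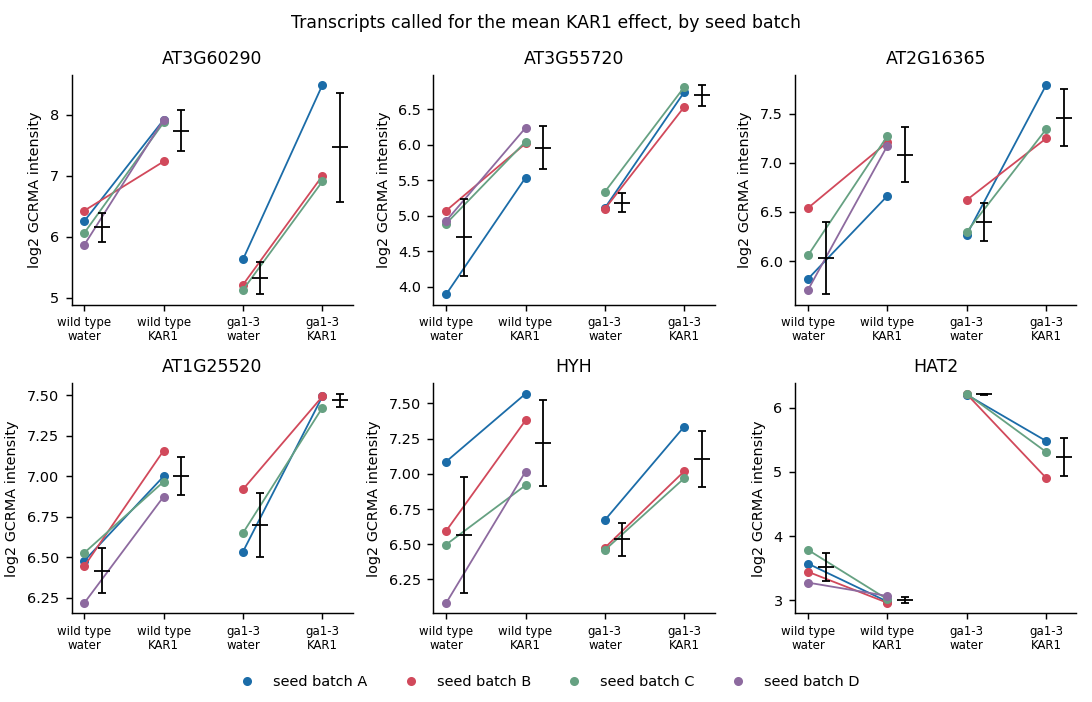
Log2 intensity on each array of 6 transcripts called for the mean KAR1 effect with or without the seed batch block; lines join the water and KAR1 arrays of 1 seed batch, and bars beside the points give mean and SD (n = 4 in wild type, n = 3 in ga1-3). Each line of AT3G60290, AT3G55720, AT2G16365, AT1G25520 and HYH goes up and each line of HAT2 goes down. Genes named by size had to move 1 way in every seed batch.

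None of the 6 fixed lists with 3 or more measured members passed the camera test for the mean KAR1 effect, and their lowest adjusted p was 0.908. Among the added lists, the dehydration, LEA and seed maturation genes shifted down (adjusted p = 0.00129, and 0.0104 without both arrays of ga1-3 batch A), a call lost with an estimated correlation (0.186). In wild type the list's median difference was 0.00 in batch A and 0.02 in B, against -0.08 in C and -0.09 in D. None of its 20 members passed without block, and XERICO alone passed with the block. Of the 3 that passed when adjusted over the list alone, HIS1-3 had a log2 difference of -0.49 and COR27 of -0.67. Plastid-encoded genes also shifted down in the camera test (adjusted p = 0.0356, and 0.850 with an estimated correlation), with 0 of 69 members called. This shift was lost without both arrays of ga1-3 batch A (0.215), and the median of these genes rose by 0.37 in wild type batch B.

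In wild type seed alone no transcript passed the limma test for KAR1, with or without the seed batch block. Array weights gave 33 calls (26 up and 7 down) and the block with the floor 77 (56 up and 21 down), so the absence of calls depends on the setting. At an unadjusted p under 0.05 there were 462 probe sets without block and 1666 with it, where 1137 were expected by chance. The smallest p among named genes belonged to AT3G55720 (log2 1.26 ± 0.24, adjusted p = 0.751), AT1G25520 (0.58 ± 0.11), AT3G11600 (0.74 ± 0.14) and AT3G14880 (0.67 ± 0.13) upward. The mean of AT3G11600 over all arrays was log2 3.78, under 16. Downward they were AT4G33960 (-0.79 ± 0.19), AT1G79540 (-0.60 ± 0.14), AT3G58060 (-0.40 ± 0.09) and, under 16 in every group, AT1G77580 (-0.37 ± 0.09). None of these passed, and each moved in 1 direction in all 4 seed batches. HYH (0.66) and GSTU27 (0.84) passed only when adjusted over the list alone.

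In ga1-3 seed no transcript passed without block. At an unadjusted p under 0.05 there were 456 probe sets without block and 1726 with the seed batch block, where 1137 were expected by chance. With the seed batch block 3 probe sets rose and none fell, array weights gave 8 calls and the block with the floor 47. The named ones were AT3G55720, which rose 2.86-fold (log2 1.51, adjusted p = 0.0489), and AT5G56980 (adjusted p = 0.0257). Each rose in 3 of 3 seed batches, as the naming rule asked. AT5G56980 lay under 16 on every array, at most at 3.34, so no fold is given. Without block the smallest p belonged to AT1G25520 (0.77 ± 0.12, adjusted p = 0.376), HAT2 (-0.98 ± 0.15, 0.376), AT3G60290 (2.13 ± 0.36, 0.458) and AT2G24240 (0.63 ± 0.11, 0.496). HIS1-3, a linker histone induced by drought, had a difference of -0.80 ± 0.20 and passed only when adjusted over the list alone. Its list of dehydration, LEA and seed maturation genes shifted down in camera (adjusted p = 0.000366, and 0.126 with an estimated correlation), as did autophagy genes (0.0119 and 0.804), with 0 members called in either. The autophagy shift lay in batch A, with a median difference of -0.75 against -0.07 in B and 0.07 in C, and was lost without that batch (0.568). The dehydration list had -0.08, -0.05 and -0.05, and 0.0279 without batch A. With the hybridisation cluster as block, 7 probe sets rose, AT3G60290 among them (adjusted p = 0.0294).

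No difference in KAR1 effect between the genotypes was detected. The interaction had 0 calls in limma without block and with the seed batch block. It had 116 and 615 probe sets with an unadjusted p under 0.05, where 1137 were expected by chance. The smallest p among named genes belonged to AT2G42300 (log2 0.56 ± 0.16) and, under 16 in every group, CR4 (0.39 ± 0.11) and AT3G13030 (-0.66 ± 0.18), none of which passed (adjusted p = 1.00). A missed threshold does not show equal effects, since the median standard error of the interaction was 0.18 without block and 0.11 with the seed batch block. Across 11373 probe sets above the median level, the KAR1 effects in wild type and in ga1-3 correlated at r = 0.563 (Spearman 0.424), and 64.2% had the same sign. Probe sets are not independent replicates, so water and KAR1 were swapped inside seed batches in all 128 ways. No other swap than the real labels and their mirror reached this r (exact permutation p = 0.0156, the smallest these swaps can give; highest other r 0.445). Without the ga1-3 water array of batch A the correlation was 0.325, a setting that leaves this batch on KAR1 only. It was 0.480 without both arrays of ga1-3 batch A and 0.567 without both of wild type batch A.

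**Figure D3:**
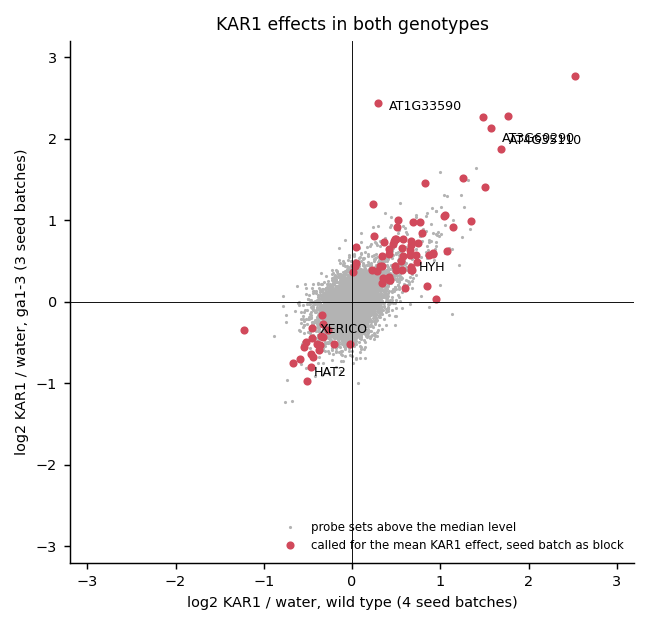
Log2 ratio of KAR1 to water in wild type (x axis, 4 seed batches) against ga1-3 (y axis, 3 seed batches); grey points are 11373 probe sets above the median level (r = 0.563) and red points the 86 called for the mean KAR1 effect with the seed batch as block.

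ga1-3 seed differed from wild type in many more transcripts. This comparison asks what lack of gibberellin changes in dormant seed on water. PRX52, a class III peroxidase, was at least 8.80-fold higher in ga1-3, at 7.14 ± 0.02 (SD, n = 3) against 2.26 ± 0.10 (SD, n = 4), with an adjusted p of 2.93e-07. EXPA4, an expansin that loosens cell walls, was at least 5.59-fold higher (adjusted p = 2.98e-08), and AT2G43580, of the chitinase family, 9.38-fold higher (3.23 ± 0.29). AT2G22590, a UDP-glycosyltransferase, was at least 9-fold higher (adjusted p = 0.00152). Its size was unsure, at a log2 bound of 2.53 to 4.26 with 1 array left out and of 0.98 in cluster 2 alone, which has only 1 ga1-3 array on water. SAG29, a sugar transporter of the SWEET family, was 6.90-fold higher (2.79 ± 0.23). The transcript of AT3G47320, a pseudogene in TAIR10.1, was at least 87.2-fold lower, at 2.89 ± 0.04 (SD, n = 3) against 10.45 ± 0.22 (SD, n = 4). PYK10, a beta-glucosidase of endoplasmic reticulum bodies, was at least 2.31-fold lower, AT1G17410, of the nucleoside diphosphate kinase family, at least 6.21-fold lower and AT5G18540 11.7-fold lower. None of these overlapped between the genotypes on any array on water, which the naming rule asked for.

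On water 8301 probe sets were called, 4474 higher and 3827 lower in ga1-3, of which 1517 differed at least 2-fold (1025 higher and 492 lower). The balance of directions changed with the setting, from 2876 higher and 1330 lower with the floor to 1731 higher and 2161 lower in cluster 2 alone. Of the calls, 3937 had no group mean above 16. On clusters 1 and 3 alone 2001 probe sets were called with at least a 2-fold difference. In cluster 2, whose 2 wild type arrays and 1 ga1-3 array on water had no part in that choice, 91.9% of them had the same direction, at a median of 0.43 times the log2 difference. Of all probe sets 52.2% were higher in ga1-3 there. With the cluster as block the count was 4191, and 666 with at least a 2-fold difference.

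**Figure D4:**
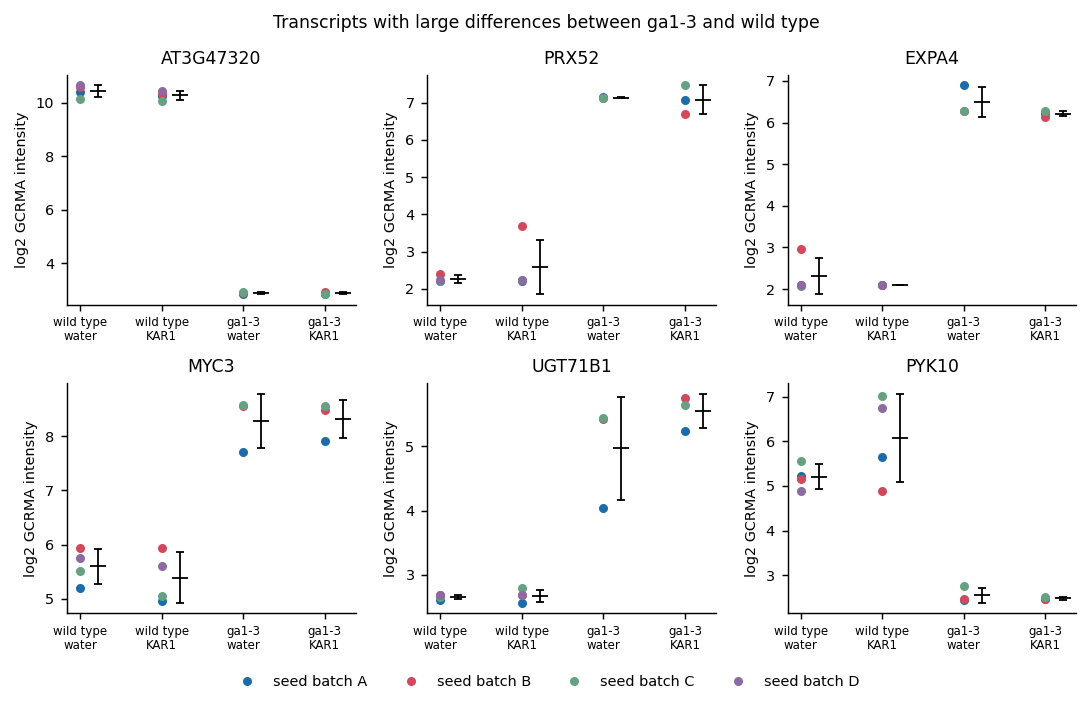
Log2 intensity on each array of 6 transcripts with large differences between ga1-3 and wild type, coloured by seed batch, with mean and SD beside the points (n = 4 in wild type, n = 3 in ga1-3). The genotypes do not overlap in any panel, and a lack of overlap was part of the rule that named these genes.

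Among the fixed lists, gibberellin signalling had 1 of 5 measured members higher in ga1-3 on water and none lower, and 4 passed when adjusted over the list alone. The gibberellin receptor gene GID1C was 1.87-fold higher (0.91 ± 0.22, adjusted p = 0.00778; 0.52 and 0.156 with the cluster as block). GID1A (0.49), SPY (0.66) and SLY1 (-0.46) passed over the list alone, and GID1A was at -0.08 within cluster 2. Cell wall loosening had EXPA4 higher, EXPA15 lower (at least 1.28-fold, adjusted p = 0.000373) and 4 of 6 members not passing. In the photosynthesis list 1 of 4 members was higher, LHCB4.3, a light-harvesting protein (2.11-fold, adjusted p = 0.00107). UGT78D2, a flavonoid glucosyltransferase, was the 1 of 3 flavonoid members that passed (2.93-fold, adjusted p = 0.0282; 0.414 with the cluster as block; lost when any 1 of 4 arrays was left out). Auxin response had 1 of 3 members lower, and lipid mobilisation 0 of 3. The lower one, WES1, lay at 2.07 on all wild type arrays and at a single lower value on all ga1-3 arrays, among the lowest intensities, where the first percentiles of the genotypes also differed (4.3 and 4.1). The only measured member of the seed storage and late embryogenesis list, LEA4-5, was lower (-0.39, adjusted p = 0.00435), and neither endosperm marker measured passed. No fixed list passed camera (lowest adjusted p = 0.664).

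Among the added lists 3 passed camera on water. Counts of members are to be read against all 22746 probe sets, of which 4474 were called higher and 3827 lower on water. UDP-glycosyltransferases, which attach sugars to hormones and secondary metabolites, had 22 of 47 members higher and 6 lower (adjusted p = 0.0141, lost with an estimated correlation at 0.874). Of these, 12 higher and 1 lower had a group mean of 16 or more. UGT78D1, which rhamnosylates flavonols, was 6.54-fold higher (log2 2.71, and 2.34 to 3.37 with 1 array left out) and UGT71B1 at least 1.96-fold higher (log2 bound 0.97, but only 0.04 in cluster 2 alone). Tubulins and actins had 6 of 9 higher and 0 lower (adjusted p = 0.0141, lost with an estimated correlation at 0.206), 3 of them with a group mean of 16 or more, with TUB7 3.98-fold and TUA1 1.58-fold higher. Plastid-encoded genes had 8 of 69 lower and 0 higher (adjusted p = 0.000318, lost with an estimated correlation at 0.874). This share of lower members is below that over all probe sets. ndhK was at least 6.28-fold and ndhG 6.97-fold lower, and petD was at a log2 difference of -2.58 or below. Mitochondrion-encoded genes had 5 of 16 higher, cox1 (2.92-fold) and nad5 (3.77-fold) among them, and 3 lower, of which 3 and 2 had a group mean of 16 or more.

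Without both arrays of wild type batch A, which had high plastid values, 17 of 69 plastid-encoded members were lower on water (camera adjusted p = 0.0143). Of all 22746 probe sets 4897 were lower in that setting, a similar share. ndhK (log2 -1.94 or below), petD (-1.73 or below) and ndhG (-2.25) were then still called, but petD lost its call without the batch A water array alone (adjusted p = 0.0845). With the cluster as block none of these 3 passed, with an adjusted p of 0.092, 0.519 and 0.361. With 1 array left out petD lost its call 4 of 7 times and ndhG 2 of 7, and petD lost it with the floor (0.0573). The 5S ribosomal RNA control was also lower in ga1-3 on water, at 7.48 ± 0.70 (SD, n = 3) against 9.45 ± 1.00 (SD, n = 4), and the actin 3' minus 5' difference was 0.76 ± 0.08 against 1.05 ± 0.27, so a difference in RNA between the genotypes is not excluded.

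On KAR1 the same comparison asks whether the genotype difference stands in seed given the compound. The differences closely followed those on water. AT2G22590 was at least 16.9-fold (log2 bound 4.08, 3.52 to 5.01 with 1 array left out and 2.23 in cluster 2 alone), PRX52 at least 8.44-fold and EXPA4 at least 4.64-fold higher in ga1-3, and MYC3, a bHLH factor of jasmonate signalling, was 7.62-fold higher (2.93 ± 0.30, adjusted p = 1.44e-05). AT1G06000, a flavonol rhamnosyltransferase, was higher by 3.17 ± 0.51 (log2) and UGT71B1 at least 2.93-fold higher. AT3G47320 was at least 77.9-fold lower, PYK10 at least 4.23-fold, AT1G17410 at least 5.95-fold and AT3G16120 6.99-fold lower. Of 8560 calls, 4397 were higher and 4163 lower, and 1661 differed at least 2-fold (1082 higher and 579 lower). The 2-fold calls on water and on KAR1 shared 862 higher and 399 lower probe sets, where independent lists would share 48.8 and 12.5. The groups behind these comparisons share no arrays, though they share seed batches. With the floor 2918 were higher and 1498 lower, while lower ones were the majority in cluster 2 alone (1882 higher and 2457 lower). With the cluster as block 4502 were called (2139 higher and 2363 lower), 776 of them at least 2-fold. Of 2102 2-fold calls made on clusters 1 and 3 alone, 92.0% had the same direction in cluster 2, at a median of 0.49 times the difference, where 50.2% of all probe sets were higher.

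The gene groups on KAR1 gave 2 of 5 gibberellin signalling members higher (GID1C 1.99-fold and GID1A 1.52-fold, which lost its call when any 1 of 3 arrays was left out). In the cell wall list EXPA15 was lower (at least 1.38-fold), as was EXPA9 with both genotypes under 16, while EXPA4 and, near the lowest intensity, XTH33 were higher. UDP-glycosyltransferases had 20 of 47 members higher and 5 lower (camera adjusted p = 0.00739, lost with an estimated correlation at 0.810), of which 12 and 1 had a group mean of 16 or more. Tubulins and actins had 6 of 9 higher (0.0306, lost at 0.317), 3 of them with such a mean, and plastid-encoded genes 16 of 69 lower (0.000221, lost at 0.810). Of all 22746 probe sets 4397 were higher and 4163 lower on KAR1. The 5S control (7.36 ± 0.85 against 9.49 ± 0.88) and the actin difference (0.66 ± 0.03 against 1.03 ± 0.15) were again lower in ga1-3. Autophagy genes had 4 of 10 members lower and none higher, all from the ATG8 family that coats autophagosomes, with ATG8H at -1.32 (adjusted p = 0.00405) and ATG8E at -0.91 (0.022); the list did not pass camera (adjusted p = 0.268). Of these 4, ATG8H alone passed with the cluster as block (0.0231), a fit that rests on ga1-3 batch A for the genotype. Its KAR1 minus water difference was -1.48 in ga1-3 batch A, against 0.17 in B and 0.19 in C. ATG8E lost its call without ga1-3 batch B or C.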

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

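The tests of explanations below were chosen after the result was seen, except the counts over other splits of the arrays and over swaps of the treatments.

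In 16 of 164 groups of 4 wild type arrays tested, 1 array's gap to the nearest of the others relative to the group's range exceeded Dixon's critical value, where chance gives about 8.2. Seed batch A was the one apart in 11 of these and batch B in 5. On KAR1, batch A stood apart for AT2G16365 (gap of 0.837 of the range), AT5G56980 (1.00), XTH33 (1.00), SPY (0.833), nad5 (0.964), AT3G16120 (0.887), the scores on principal components 1 (0.831) and 2 (0.848), and the array's median (0.895); for AT5G56980 and XTH33 the other 3 arrays held 1 and the same value. On water, batch A stood apart for AT3G55720 (0.845), at 3.90, and for SWEET6 (0.885). Batch B stood apart on water for PRX52 (0.848), EXPA4 (0.962) and the 3' minus 5' difference of the GAPDH control (0.899), and on KAR1 for AT3G60290 (0.932), at 7.23, and PRX52 (0.979), at 3.69.

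The difference between ga1-3 and wild type exceeds what regrouping the arrays gives: 1 of 35 splits of the arrays on water, the real one, had 8301 calls or more (highest other 2808), and 1 of 35 on KAR1 had 8560 or more (highest other 872). With the cluster as block, 36.6% of the 2-fold calls on water stayed 2-fold calls in the same direction. This share is partly fixed, since cluster 2 helped choose these calls and alone informs the genotype difference in that fit. Of the 2-fold calls chosen on clusters 1 and 3 alone, 91.9% had the same direction in cluster 2, where 52.2% of all probe sets were higher. This goes against the cluster as the whole cause, as far as 1 ga1-3 array on water can show. With a floor of log2 4, 69.02% stayed 2-fold calls, and for these the values under 16 are not the whole cause. The floor cannot speak to normalization above 16. The limit of 10% for both shares was set with the counts known. For the 3937 calls on water whose group means all lie under 16, normalization may be the cause, since the first percentile was 4.1 on every ga1-3 array and 4.3 on every wild type array, ga1-3 batch A included. The 99th percentile also set the genotypes apart, at 4417 to 4676 in wild type and 5012 to 5344 in ga1-3. Probe sets with a group mean of 16 or more had a median log2 difference of 0.159 on water. A difference in normalization may therefore reach calls above 16 as well. With quantile normalization 4125 were called higher and 3364 lower on water. What share of each difference belongs to the cluster stays open, because cluster 3 holds ga1-3 alone. Gibberellin deficiency and any other difference between the seed stocks also stay open.

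Seed batch A of ga1-3 lay 60.8% of the way from wild type to batches B and C on principal component 1. Wild type seed in the batch would bring every transcript high in wild type at about 1 share, and a first test asked whether 25% or more of 23 such transcripts stood at a share under 0.05. Only 8.70% did (2 of 23; median share 0.219, quartiles 0.133 and 0.587), which left a mixture open. AT3G47320 was then singled out in a test put beside the first one after that outcome. Its share of -0.00017 argues against wild type seed, as far as 1 transcript can. The hybridisation cluster and the seed batch cannot be told apart here, since no wild type array shares the cluster of batches B and C (r of 0.193 between the step of batch A in ga1-3 and the step of C and D over B in wild type), and no biological explanation was tested.

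Plastid-encoded transcripts were high in both arrays of wild type batch A. The hybridisation cluster is argued against by batch B of the same cluster, whose plastid median was lower (-1.72 against batch A). More RNA without a poly(A) tail in general is argued against by the mitochondrion-encoded transcripts, which rose in batch A by 0.229 times as much as the plastid ones, although the 5S ribosomal RNA control was also higher, by 1.52. RNA degradation is argued against by the 3' minus 5' differences of actin and GAPDH, of which 2 of 2 lay inside the range of the other wild type arrays in both arrays of batch A. A difference between the harvests of seed may remain as a hypothesis, and it was not tested.

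For KAR1 in wild type the real labels gave 0 calls, a count that each of the 35 splits reaches, so this test says nothing about chance; 1 split gave 176 calls. That split sets water A and C with KAR1 A and D against the others. For KAR1 in ga1-3 there are 10 splits, too few for a share under 0.05 (real 0, highest other 1). For the interaction the real count is also 0, which each of the 100 splits drawn reaches, so this test says nothing either (highest other 91). For the mean KAR1 effect without block 4 of 100 splits drawn gave 5 calls or more; the highest other, 157, and 2 with 66 calls each used the wild type split named above. With the seed batch as block, 1 of 64 ways to swap water and KAR1 inside seed batches, the real one, gave 86 calls or more, and the other 63 gave 0.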

How the results depend on the processing

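Alternatives with or without a hybridisation cluster, with both arrays of a seed batch left out, with the floor and a block or fold limit together, and the 15 further lists (built before any effect was looked at) were added after seeing the arrays' values; the others were planned. Total counts of calls not named here stayed within 1.5 times those reported, while counts by direction and at an unadjusted p moved more in places, and the cause of the changes was not tested except where a setting by construction tests fewer arrays or asks for more. With the seed batch as replicate block, KAR1 gave 0 calls in wild type, 3 in ga1-3, 0 in the interaction and 86 in the mean effect; the letter as block across genotypes, which pairs no seed (r of 0.0371 to 0.349 between the genotypes of a letter), gave 9863 on water and 10112 on KAR1 for the genotype. With the cluster as block these were 0, 7, 1, 27, 4191 and 4502. Array weights gave 33 calls for KAR1 in wild type, 8 in ga1-3, 90 in the mean and 12659 and 12925 for the genotype.

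For the mean KAR1 effect (5 calls), plain eBayes gave 1, leaving out the 7582 lowest probe sets 9, centring on the median 2, the floor 12 and a 2-fold limit 3. Quantile normalization gave 5 up and 0 down and centring 2 up and 0 down, against 4 up and 1 down. For KAR1 in ga1-3 the floor gave 3 calls and the compared arrays alone 1. The block with the floor gave 77 in wild type, 47 in ga1-3, 1 in the interaction and 477 in the mean. Without both arrays of wild type batch A the counts were 1 in wild type, 1 in ga1-3 and 3 in the mean; without both of ga1-3 batch A, 6 in ga1-3, 2 in the interaction and 13 in the mean. Leaving out 1 array at a time, without block, gave 0 to 3 calls for KAR1 in ga1-3, 0 to 1 in the interaction and 0 to 7 in the mean. The mean had 0 without wild type water C, wild type KAR1 C or D, or ga1-3 water A or C, and 1 without wild type water A or ga1-3 KAR1 B.

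For the genotype, centring gave 4032 calls on water and 4386 on KAR1, the floor 4206 and 4416, a 2-fold limit 1517 and 1661, clusters 1 and 3 alone with it 2001 and 2102, cluster 2 alone 3892 and 4339, the cluster block with a 2-fold limit 666 and 776, and the floor with it 1066 and 1201. Leaving out the lowest probe sets took the lower calls from 3827 to 1972 on water and from 4163 to 2198 on KAR1. Leaving out 1 array gave 5700 to 8689 on water and 6135 to 8534 on KAR1. Quantile normalization and centring shifted an array's median by up to 0.188 and 0.189. The correlation of KAR1 effects was 0.997 over called probe sets alone and 0.325 to 0.550 without 1 array, lowest without ga1-3 water A. Without both arrays of ga1-3 batch A it was 0.480, and without both of wild type batch A 0.567. For the fixed lists camera gave 0 calls and fry 8; for the added lists camera gave 10 and fry 9, and none held with an estimated correlation. Camera on the added lists gave 9 without both arrays of wild type batch A and 8 without both of ga1-3 batch A.

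Among named genes, 8 values reversed, 7 of them near the lowest intensity. EXPA7 on water was 0.0352 with quantile normalization and 0.000547 with centring, and on KAR1 0.0107 with quantile normalization. EXPA18 was 0.0195 on water and 0.0213 on KAR1 with quantile normalization and 0.0014 on KAR1 with centring. SWEET9 on KAR1 was 0.0030 with quantile normalization, and GID1A on water was -0.0796 in cluster 2 alone. Of the other values of named genes under an alternative, 375 on water and 417 on KAR1 lost the genotype call in the same direction, 55 lost and 64 gained the mean KAR1 call. Signal over background limits the 3937 and 3996 genotype calls whose group means all lie under 16.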

Other observations

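The test of an opposed KAR1 and genotype effect and the test across seed batches were chosen before their result was seen; the swap test of the correlation and the test of neighbouring genes were chosen after their result was seen.

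The glutathione S-transferase GSTL3 was at least 1.35-fold higher in ga1-3 on water and at least 1.41-fold on KAR1. The beta-glucosidase BGLU25 was 3.04-fold and 3.24-fold higher, while PYK10 of the same family was lower. The rubisco activase gene RCA was at least 1.87-fold higher on water and 1.84-fold on KAR1, although nuclear photosynthesis genes went both ways on water, with 10 of 34 higher and 9 lower. Plastid RNA editing factors had 3 of 13 members higher on water and 4 on KAR1, with none lower. Of all 22746 probe sets 4474 and 4397 were higher. The list was built from gene names, so not every member need act in plastids. OTP43, higher on both treatments, and OTP85, higher on KAR1, had both genotype means under 16. OTP81 was higher by 1.32 and 1.72 (log2). With the hybridisation cluster as block, which rests on ga1-3 batch A for the genotype, GSTL3, BGLU25 and RCA passed on both treatments. OTP81 passed on KAR1 alone (adjusted p = 0.0434, and 0.413 on water), and its call on water was lost without ga1-3 batch B or C.

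Other added lists, all but the last given here, held members that went both ways on water, many of them under 16. Expansins and xyloglucan endotransglucosylases had 4 of 28 higher and 8 lower, DNA replication, histone and mitosis genes 3 of 19 and 4, and amino acid and lipid catabolism 3 of 14 and 1. Pollen and reproductive genes had 4 of 20 higher and 2 lower and glutathione S-transferases 6 of 14 and 2. Of all 22746 probe sets 4474 were higher and 3827 lower on water. The list of SWEET sugar transporters, which leaves out SAG29 because its name differs, had 0 of 14 higher and 1 lower, SWEET6 (-0.92), whose call was lost when any 1 of 4 arrays was left out.

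A first hypothesis was that KAR1 moves the seed against the ga1-3 difference. The mean KAR1 effect and the mean genotype difference correlated across 11281 probe sets at r = 0.273, above 0, and of 29 KAR1 calls with a genotype call 22 had the same sign and 7 the opposite one. The hypothesis was not borne out (exact permutation p = 0.883 over 128 swaps).

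A second hypothesis was that the KAR1 response recurs in every seed batch. The difference of each of the 7 seed batches correlated above 0 with the mean effect in the other genotype, from 0.225 in wild type batch B to 0.590 in batch D. A response that recurs across harvests and both genotypes would give this. The share of 0.0156 of swaps with an r as high for the genotype means rests on the same differences, so it is no separate support.

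Another hypothesis was that transcripts without overlap between the genotypes mark a chromosome segment that differs. Of 13217 measured genes, 45 had every ga1-3 array at least 2-fold below every wild type array. Among these, 2 pairs lay within 5 measured genes of each other in the order of TAIR10.1, against 0.742 for random genes (permutation p = 0.169). The 71 genes higher in ga1-3 by such a gap gave 2 pairs against 1.87 (permutation p = 0.568). Both leave the question open.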
